A study of Homo sapiens with 6 samples.

How the data were processed

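Total RNA from 6 samples of MCF-7 clones was labelled with biotin and hybridised to Affymetrix expression arrays, 3 arrays for clone 6A-SA5 and 3 for clone WT-WB1. The deposited table held log2 values for 54675 probe sets, made with RMA per the submitters' processing notes. RMA subtracts background, normalizes between arrays and summarises the probes of a probe set. The RMA version and which arrays were normalized together are not given in the sources used here. RMA gives no detection call, so a low value could not be separated from background, and cross-hybridisation was not measured. Values on the 6 arrays ran from 3.29 to 14.53, with array medians between 6.82 and 6.87. No further normalization was applied in the main analysis. Arrays have no sequencing depth, and their number, 3 for each clone, limits the precision.

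Samples were grouped by clone as named in their labels. The sources name 1 clone for each construct, and the labels do not say whether the 3 samples of a clone came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. No file pair was identical: correlations within a clone ranged from 0.9974 to 0.9984.

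Probe sets were named from the platform annotation. Of the 54613 probe sets left after 62 Affymetrix controls were set aside, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Of the symbols on the first group, 41037 matched the current RefSeq gene table (GRCh38.p14), and 0 needed an update. Probe sets with several symbols or none were tested but were not assigned to a gene. A gene was represented by its probe set with the highest mean over all 6 arrays, which gave 19775 genes. The RefSeq table was used for names and for the order of neighbouring genes, and no coordinates were taken from it because the array files name no genome build.

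Each probe set was tested with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), two-sided, 6A-SA5 minus WT-WB1, with Benjamini-Hochberg adjustment over all 54613 probe sets. The threshold was an adjusted p under 0.05, with a further count at a change of at least 2-fold. An adjusted p of a gene in the text comes from this fit unless a setting is named beside it, in which case it comes from the fit in that setting, and folds are 2 to the power of the log2 difference. RMA compresses differences of dim probe sets, so their folds are understated.

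The gene lists were fixed before the data were examined, 25 in all: TGF-β/SMAD target genes; TGF-β family receptors, ligands and SMADs; Rho GTPases and their regulators; actin cytoskeleton; extracellular matrix; integrins and focal adhesions; matrix-degrading proteases and their inhibitors; epithelial junctions; mesenchymal and EMT genes; estrogen receptor targets; luminal genes; basal and myoepithelial genes; G1/S and G2/M cell cycle genes; insulin and growth factor signalling; immediate early genes; interferon-stimulated genes; inflammatory cytokines and NF-κB targets; unfolded protein and ATF4 response; hypoxia and glycolysis; cholesterol and fatty acid synthesis; p53 targets and apoptosis genes; and markers of fibroblasts, leukocytes and endothelium. Each was tested against all other genes with camera at its preset correlation of 0.01, adjusted over the 25 lists, and again with a correlation estimated from the data. The latter has 4 residual degrees of freedom to work with. Members were also counted with p-values adjusted over the list alone. A second list of p53 targets and a list of NRF2 targets were added after the main results were seen, for the closing section.

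The rule for named genes was also fixed beforehand. It took genes with an adjusted p under 0.05, a change of at least 2-fold, all 3 arrays of one clone above all 3 of the other, and a mean in the higher clone above 6.85, the median of all probe set means. The 12 largest differences in each direction were named. TGFBR1, TGFBR2, ARHGAP5, FN1 and RHOA were named whatever their values, as were the 3 members of each list with the smallest p where these passed the threshold. This gave 92 genes. Other genes in the text are further members of these lists, chosen after their values were seen, or genes that serve as landmarks.

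Genes were put in the order of the RefSeq table, keeping the 13174 genes brighter than the table median. Medians of the log2 difference were taken over windows of 20 consecutive genes, and windows beyond the limits given by shuffling the gene order 1000 times were joined into runs.

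The alternatives were a trended and robust eBayes fit, quantile normalization repeated on the 6 arrays, subtraction of array medians, removal of dim probe sets, removal of probe sets whose identifier ends in _x_at or _s_at (designs that can match several transcripts), the replicate number as a block, leaving out each array in turn, an adjusted p under 0.01, the mean of all probe sets of a gene, an estimated correlation in camera, and fry in place of camera. Removal of genes in shifted runs was added later. Figures were drawn with matplotlib 3.10.9.

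The fit was tested on simulated data: 200 of 54613 probe sets, with the means and spreads of the real arrays, were changed in 6A-SA5 against WT-WB1. At a log2 size of 0.25, 2% of the 50 planted probe sets were recovered. The shares were 52% at 0.5, 94% at 1 and 100% at 2, with mean estimates of 0.25, 0.49, 1.01 and 1.99. Recovery of 95% at a size of 1 had been required first and was missed, and the requirement was then moved to a size of 2. Of 128 calls, 4 were not planted. Only 200 probe sets were changed, whereas 11.6% of probe sets were called in the real data. With so few changes the adjusted threshold is stricter, so these shares do not give the recovery in the real data. A shift planted in 1 of the 25 lists was the 1 list called. The noise was drawn independently for each probe set, so this could not show how correlation between genes affects camera's calls. A run of 40 neighbouring genes was found whole, within a called run of 61, so the ends of runs are blurred by the window.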

Results

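Transcript levels were measured in a pair of clones of MCF-7, an estrogen receptor-positive human breast cancer cell line. Clone WT-WB1 carried a stably transfected, tagged copy of TGFBR1, the type I receptor of TGF-β. Clone 6A-SA5 carried TGFBR1*6A, a form of the same receptor with a shortened run of alanines near its start. Cells were starved of serum overnight and then given medium with 10% serum for 18 h before RNA was taken, without any added growth factor. Each clone was measured on 3 arrays. Arrays of the same clone correlated at 0.9974 to 0.9984 across probe sets, and arrays of different clones at 0.9936 to 0.9945. The first principal component held 62.3% of the variance and separated the clones. The second held 13.7% and mainly set replicate 1 of 6A-SA5 apart, with a score of 20.1 against −11.3 to 6.28 on the other 5 arrays.

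The comparison asked which genes differed between the clones under the conditions of a migration assay, because the submitters describe the *6A clone as more migratory and invasive without TGF-β. Most of the large differences were lower levels in 6A-SA5. The Golgi mannosidase MAN1A1 was 18.2-fold lower in 6A-SA5 (5.84 ± 0.22 against 10.02 ± 0.07 log2 units, SD, n = 3 arrays), and the growth hormone receptor GHR was 14.8-fold lower. The largest increase among named genes was in SLC6A14, an amino acid transporter, which was 19.9-fold higher (10.05 ± 0.03 against 5.73 ± 0.09). Among the gene groups, every member of the G2/M list that passed the test was higher. Nearly every passing member was lower in the lists of p53 target and apoptosis genes, matrix proteases and their inhibitors, and focal adhesion genes.

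Of 19775 genes, 1491 were higher and 1531 lower in 6A-SA5 at an adjusted p under 0.05. Only 18 of the former but 111 of the latter changed at least 2-fold. Among the 54613 probe sets, 3302 were higher and 3053 lower, and 36 and 207 of these changed at least 2-fold, so that 85.2% of the large differences were decreases. All 3 arrays of one clone lay above all 3 of the other for 27% of the probe sets, against 10% by chance. With 1 clone of each construct and no untransfected or empty-vector array among these samples, a difference between the receptor forms could not be separated from a difference between the clones. Without replicate 2 of 6A-SA5, 970 genes and 2134 probe sets were higher, more than 1.5 times fewer.

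**Figure D1:**
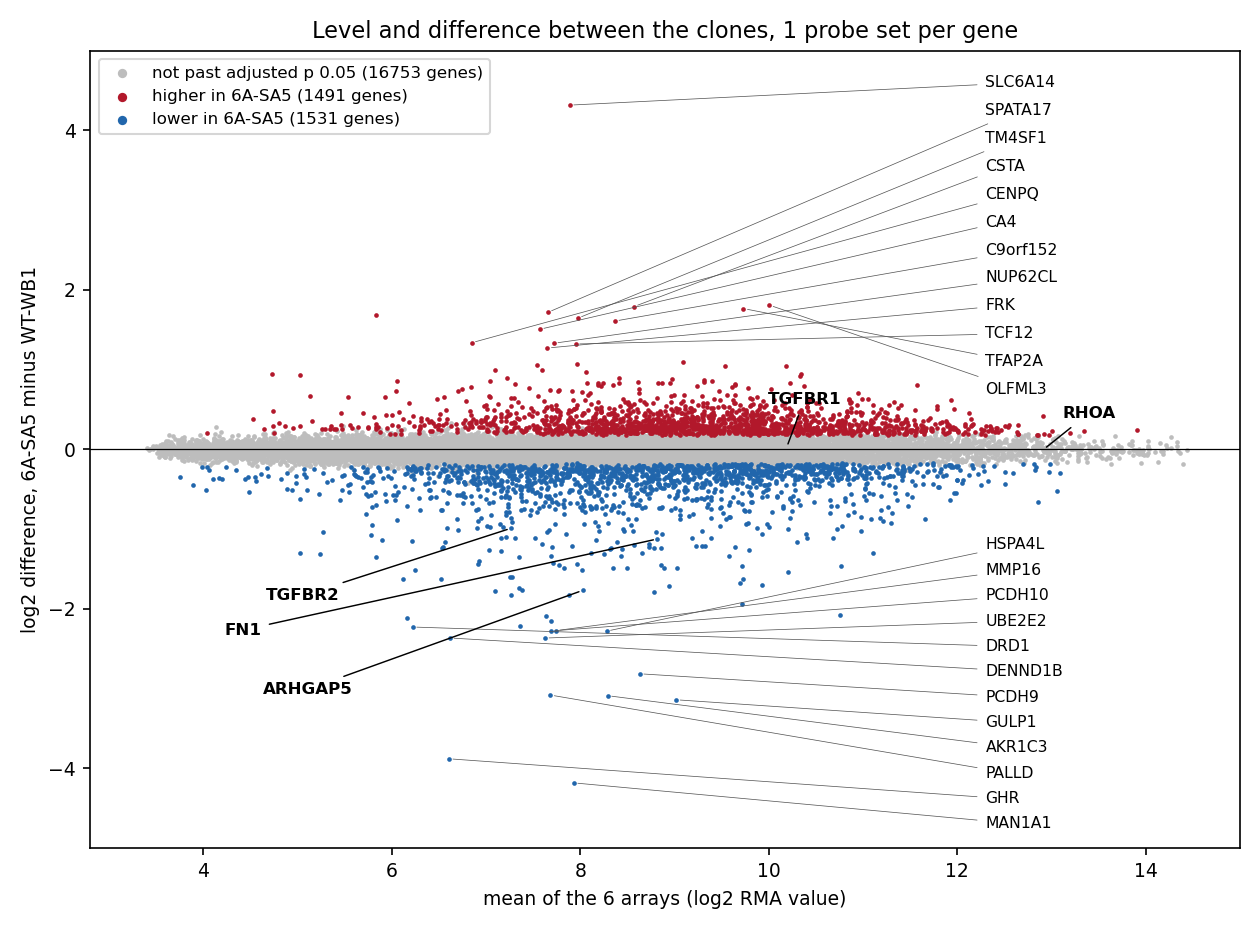
Each point is 1 gene, with the mean of its 6 log2 RMA values on the x axis and the log2 difference, 6A-SA5 minus WT-WB1, on the y axis; red and blue points passed an adjusted p of 0.05 (limma). The points extend to −4.18 (MAN1A1) and 4.32 (SLC6A14), TGFBR1 and RHOA lie near 0, and large decreases outnumber large increases.

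After SLC6A14, the higher genes were led by OLFML3, a secreted olfactomedin-domain protein (3.50-fold, adjusted p = 1.73e-07), the cysteine protease inhibitor CSTA (3.46-fold) and the transcription factor TFAP2A (3.40-fold). SPATA17 (3.29-fold), the tetraspanin-like membrane protein TM4SF1 (3.12-fold) and C9orf152 (3.05-fold) followed. Carbonic anhydrase CA4 was 2.84-fold higher, the kinetochore gene CENPQ 2.52-fold, NUP62CL 2.51-fold, the tyrosine kinase FRK 2.41-fold, and the transcription factor TCF12 had a log2 difference of 1.32. TFAP2A, CA4 and TCF12 lay in runs of neighbouring genes that were shifted upward together, a pattern described among the additional observations. CENPQ fell just below the brightness required for ordering, so whether it lay in a run was not assessed. NUP62CL lost its call without _x_at and _s_at probe sets (log2 difference 0.20, adjusted p = 0.0677), and CA4 moved from 1.51 to 0.80. As the mean of all its probe sets, TCF12 differed by 0.36, TFAP2A by 1.10 and NUP62CL by 0.77, each past the threshold.

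Below MAN1A1 and GHR, the lower genes were led by GULP1, an adaptor for the engulfment of apoptotic cells (8.83-fold), the aldo-keto reductase AKR1C3 (8.52-fold, adjusted p = 1.21e-09) and the actin-bundling protein PALLD (8.47-fold). The protocadherins PCDH9 and PCDH10 were 7.04-fold and 4.86-fold lower. The ubiquitin-conjugating enzyme UBE2E2 (5.16-fold), DENND1B (5.16-fold), the chaperone HSPA4L (4.86-fold), the membrane-type metalloprotease MMP16 (4.84-fold) and the dopamine receptor DRD1 (4.69-fold) completed the 12. MMP16 lay in a run of neighbouring genes shifted downward. GHR, DENND1B and DRD1 were too dim on average to be ordered, so they were not assessed for runs. AKR1C3 has close paralogs in AKR1C1 and AKR1C2, so its probe set may share signal with them. The log2 difference of PALLD was −0.24 without _x_at and _s_at probe sets, against −3.08. That value came from a dim probe set with means of 4.40 in 6A-SA5 and 4.63 in WT-WB1. The brighter PALLD probe sets, all ending in _s_at, differed by −3.08, −2.43 and −1.03. Averaged over all their probe sets, the differences were −1.69 for PALLD, −1.77 for GULP1, −1.69 for PCDH9, −1.22 for PCDH10, −0.79 for DENND1B and −0.92 for MMP16, all past the threshold. These averages include dim probe sets, where RMA compresses differences.

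TGFBR1, the transfected gene, did not differ between the clones on any of its 3 probe sets. The log2 differences were 0.02 (95% interval −0.13 to 0.17, adjusted p = 0.93), 0.09 (adjusted p = 0.686) and −0.14 (adjusted p = 0.495). Where these probes lie relative to the transfected sequence was not known here, so the values check neither the expression of the transgenes nor the *6A form. TGFBR2, the type II receptor that pairs with TGFBR1, was 1.99-fold lower in 6A-SA5 (6.77 ± 0.15 against 7.76 ± 0.14, adjusted p = 2.77e-05) and differed by −0.62 as the mean of its probe sets. ARHGAP5, a GTPase-activating protein that turns off Rho, was 3.41-fold lower (adjusted p = 3.11e-08), and 3 of its 5 probe sets were called with log2 differences from −1.77 to −1.48. The other pair had means near 4.15 and 4.28 and was not called, and the mean over all 5 was −1.0. RHOA itself did not differ (log2 difference −0.01, 95% interval −0.12 to 0.11, adjusted p = 0.974). The matrix glycoprotein fibronectin, FN1, was 2.18-fold lower (adjusted p = 6.69e-07), with 5 of its 7 probe sets called lower. All 5 end in _x_at or _s_at, and without them FN1 had a log2 difference of −0.04 (adjusted p = 0.843) from a dim probe set. Its probe sets averaged −0.74, against −1.12 for the brightest.

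**Figure D2:**
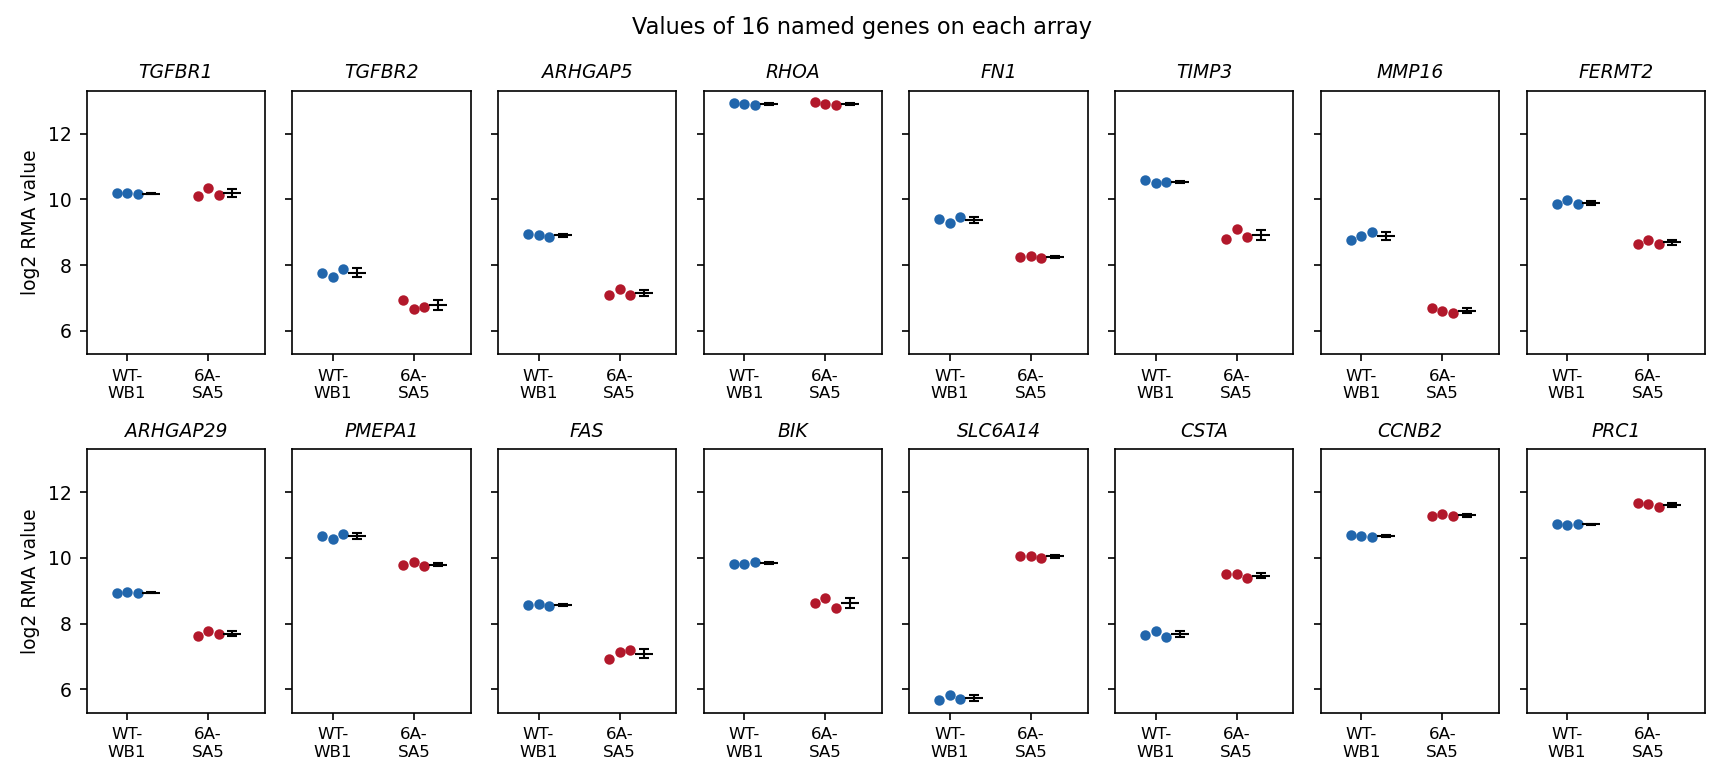
Log2 RMA values (y axis) of 16 named genes on each array of WT-WB1 (blue) and 6A-SA5 (red), 1 point per array, with the mean and SD of the 3 arrays in black. The arrays of TGFBR1 and RHOA overlap between the clones, whereas those of the other genes do not.

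Genes that act at the contact between cell and matrix were mostly lower in 6A-SA5 where they passed the test. Of 39 measured matrix-degrading proteases and inhibitors, 15 were lower and 1 higher (17 and 1 when adjusted over the list alone; camera adjusted p = 2.47e-05, and adjusted p = 0.234 with an estimated correlation). They held both proteases and their inhibitors: MMP16 and MMP9 (1.39-fold), the serine protease KLK6 (2.04-fold) and heparanase HPSE (1.51-fold) were lower, and so were the inhibitors TIMP3 (3.08-fold), TIMP2 (1.98-fold) and SERPINE2 (1.52-fold). The sheddase ADAM10 was the 1 member that was higher (1.34-fold). TIMP3 and ADAM10 lay in runs of neighbouring genes shifted in their own direction. Of 36 integrin and focal adhesion genes, 14 were lower and 1 higher (16 and 1 over the list alone; camera adjusted p = 0.000115, and adjusted p = 0.234 with an estimated correlation). FERMT2, a kindlin that activates integrins, was 2.32-fold lower, the scaffold NEDD9 1.64-fold and PARVB, a parvin that links integrins to actin, 1.43-fold, the last in a downward run. NEDD9 lay among neighbours that shifted upward, and without _x_at and _s_at probe sets its log2 difference was −1.25 instead of −0.72, and as the mean of all its probe sets −0.46. Integrin β1, ITGB1, was the exception (1.20-fold higher) and lay in an upward run.

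Extracellular matrix genes were lower for 7 of 38 and higher for 0, with the same counts over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.395 with an estimated correlation). Besides FN1 these included the fibrillar collagens COL5A1 (1.90-fold), COL5A2 (1.49-fold) and COL3A1 (1.33-fold), the last of which lost its call without _x_at and _s_at probe sets (log2 difference −0.09, adjusted p = 0.495) and differed by −0.22, against −0.41, as the mean of its probe sets. COL5A2 (5.73 in 6A-SA5 against 6.30 in WT-WB1) and COL3A1 (6.25 against 6.65) were dim, below the median of all probe set means. Their signal could not be separated from background. Mesenchymal and EMT genes were lower for 4 of 25 and higher for 0 (likewise over the list alone; camera adjusted p = 0.02, and adjusted p = 0.234 with an estimated correlation). The 4 were FN1, the ecto-nucleotidase NT5E (1.52-fold), smooth muscle actin ACTA2 (1.30-fold, or a log2 difference of −0.17 as the mean of its probe sets) and the cadherin CDH11 (1.15-fold). Without _x_at and _s_at probe sets, neither list was called (adjusted p = 0.165 and adjusted p = 0.204), with 4 and 2 members lower. As means of all probe sets 7 EMT genes were lower. Epithelial junction genes were not called as a group (5 higher and 4 lower of 30, 7 and 5 over the list alone, camera adjusted p = 0.782), with a median of −0.03 and a mean of 0.02. Without replicate 2 of WT-WB1 2 were lower, and with trended and robust eBayes 8 were higher. Within it the desmosomal genes DSC2 (log2 difference 0.59), DSG2 (0.49) and PKP2 (0.36) were higher, and claudin CLDN1 (−0.37) was lower.

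Among Rho GTPases and their regulators, 7 of 39 were lower and 2 higher (8 and 3 over the list alone, camera adjusted p = 0.0931). After ARHGAP5, the largest decreases were in ARHGAP29, another GTPase-activating protein (2.37-fold), and DIAPH2, a formin that nucleates actin filaments (2.16-fold). The probe sets of ARHGAP29 averaged to a log2 difference of −0.35, against −1.25 for the brightest. DLC1, also a GTPase-activating protein for Rho, was 1.38-fold higher, so the regulators moved both ways. Without _x_at and _s_at probe sets the list was called lower (adjusted p = 0.0121), as it was without genes in shifted runs (adjusted p = 0.0453) and by fry (adjusted p = 0.00137). With an estimated correlation camera did not call it in these settings (adjusted p = 0.205 and adjusted p = 0.3), and 1 member was higher without _x_at and _s_at probe sets. Actin cytoskeleton genes were lower for 6 of 31 and higher for 1 (7 and 1 over the list alone, camera adjusted p = 0.0527), and the list was called lower after repeated quantile normalization (adjusted p = 0.0327) and with the replicate block (adjusted p = 0.0455). It was also called without replicate 2 (adjusted p = 0.0384) or 3 (adjusted p = 0.0439) of 6A-SA5 or replicate 1 of WT-WB1 (adjusted p = 0.0472), without genes in shifted runs (adjusted p = 0.0252) and by fry (adjusted p = 0.00323). With an estimated correlation none of these camera calls held (adjusted p from 0.157 to 0.544). The lower members numbered 3 without replicate 2 of 6A-SA5, replicate 2 or 3 of WT-WB1, or _x_at and _s_at probe sets. The higher ones numbered 3 with trended and robust eBayes and 2 as means of all probe sets. Gelsolin, GSN, which severs actin filaments, was 1.92-fold lower, but lost its call without _x_at and _s_at probe sets (log2 difference −0.08, adjusted p = 0.627) and differed by −0.28 as the mean of its probe sets. Tropomyosin TPM1 was 1.42-fold higher in an upward run. Its log2 difference of 0.51 became 0.27 without _x_at and _s_at probe sets and 0.34 as the mean of all, both past the threshold. Non-muscle myosin MYH9 was 1.27-fold lower in a downward one.

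TGF-β/SMAD target genes were lower for 10 of 28 and higher for 3 (17 and 3 over the list alone; camera adjusted p = 0.000802, and adjusted p = 0.234 with an estimated correlation). TIMP3, ID3 (log2 difference −0.85) and PMEPA1, a SMAD-induced inhibitor of the pathway (−0.86), had the smallest p-values. SMAD7 (1.15-fold) and the cell cycle inhibitor CDKN1A (1.29-fold) were lower too, whereas ID2 was 1.78-fold and TPM1 1.42-fold higher. The list was not called without _x_at and _s_at probe sets (adjusted p = 0.0646), where 3 members were lower. The receptors, ligands and SMADs were not called as a group by camera (3 higher and 7 lower of 29, 3 and 8 over the list alone, adjusted p = 0.345), but fry called them lower (adjusted p = 0.0175). Their median was 0.00 while their mean was −0.06. Only 4 were lower without replicate 3 of 6A-SA5 or any 1 array of WT-WB1, and 1 was higher without replicate 2 of 6A-SA5 or replicate 3 of WT-WB1. The ligand gene TGFB2 was 1.37-fold lower and TGFB3 1.34-fold higher, with a log2 difference of 0.23 as the mean of its probe sets against 0.42.

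**Figure D3:**
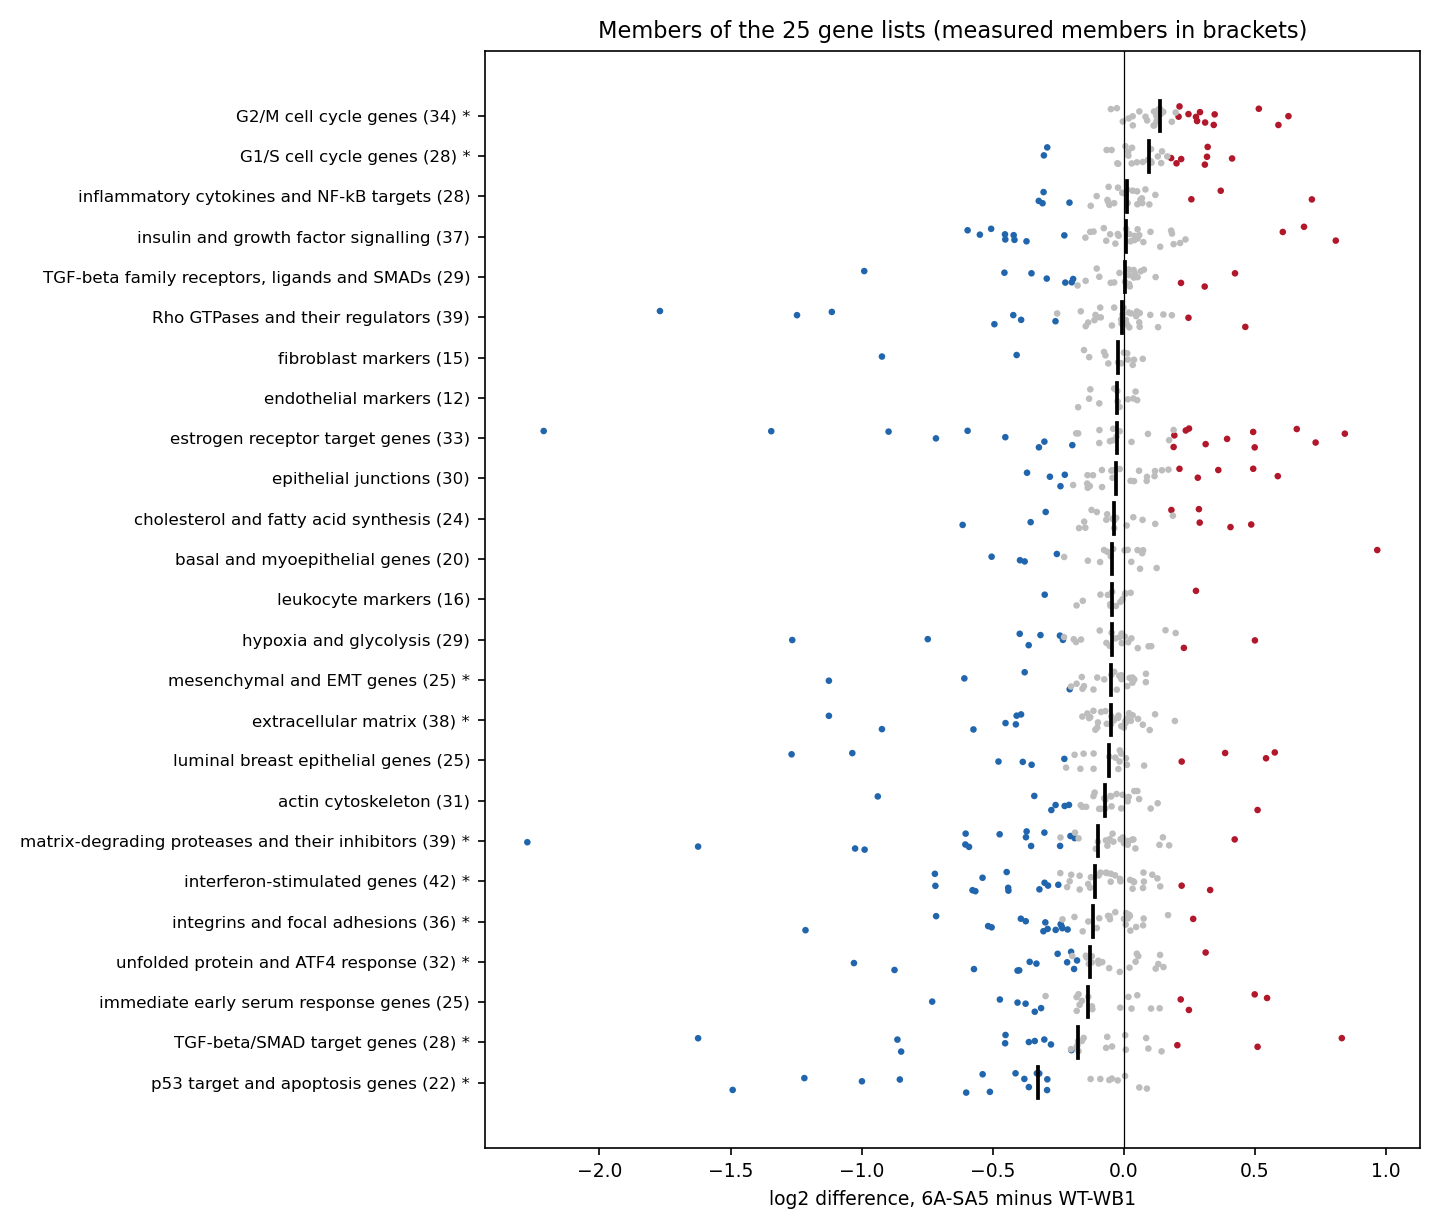
Log2 difference, 6A-SA5 minus WT-WB1 (x axis), of each measured member of the 25 gene lists (y axis, number measured in brackets); red and blue points passed an adjusted p of 0.05, black bars are list medians, and an asterisk marks lists with a camera adjusted p under 0.05 at the preset correlation. The p53 target and apoptosis list has the lowest median, −0.33, and the G2/M list the highest, 0.14.

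Cell cycle genes that passed the test were mostly higher in 6A-SA5, by small amounts. Of 34 G2/M genes, 12 were higher and 0 lower (15 and 0 over the list alone; camera adjusted p = 3.82e-09, and adjusted p = 0.234 with an estimated correlation). The log2 difference was 0.63 for cyclin CCNB2, 0.59 for the spindle midzone protein PRC1, 0.51 for the checkpoint kinase BUB1B and 0.28 for MKI67, the proliferation marker Ki-67. Averaged over its probe sets, CCNB2 differed by 0.26. The higher G2/M genes numbered 7 without _x_at and _s_at probe sets and 19 with trended and robust eBayes. CCNB2 and 3 further members (KIF23, NUSAP1 and ECT2) lay in upward runs, and the 30 members outside runs had a median of 0.13. Of 28 G1/S genes, 7 were higher and 2 lower (8 and 2 over the list alone; camera adjusted p = 0.00336, and adjusted p = 0.395 with an estimated correlation), but 4 were higher without replicate 1 or 2 of WT-WB1, and 1 was lower as means of all probe sets. Ribonucleotide reductase RRM2 was 1.33-fold, MCM3 1.24-fold and CDC45 1.25-fold higher, whereas MCM5 (1.24-fold) and cyclin CCNE1 (1.22-fold) were lower. MCM3 and MCM5 lay in runs shifted in their own direction.

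The p53 target and apoptosis list had the largest shift, a median log2 difference of −0.33. Of its 22 measured members, 14 were lower and 0 higher, also over the list alone (camera adjusted p = 2.59e-09, and adjusted p = 0.234 with an estimated correlation). The death receptor FAS was 2.81-fold lower (7.08 ± 0.14 against 8.57 ± 0.03), the BH3-only gene BIK 2.33-fold and the cytokine gene GDF15 2.00-fold. TP53INP1 (1.81-fold), RRM2B (1.52-fold), MDM2 (1.22-fold) and CDKN1A were among the others. BIK, TP53INP1 and RRM2B lay in downward runs. FAS was called lower on 4 probe sets, all of which end in _x_at or _s_at. Without these the log2 differences were −0.04 for FAS (adjusted p = 0.88) and −0.19 for GDF15 (adjusted p = 0.137), and 8 members of the list were called lower. The mean of all its probe sets was −0.41 for GDF15, and 1 member was higher in that setting.

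Among stress genes, 12 of 32 members of the unfolded protein and ATF4 response were lower and 1 higher (13 and 2 over the list alone; camera adjusted p = 0.000802, and adjusted p = 0.381 with an estimated correlation). Without replicate 3 of either clone 7 were lower. The higher members numbered 4 with trended and robust eBayes, 2 among bright probe sets and 0 as means of all probe sets. The mTORC1 inhibitor DDIT4 was 2.04-fold, the cystine transporter SLC7A11 1.83-fold and VLDLR 1.49-fold lower. ATF4 itself was 1.19-fold lower, in a downward run, while XBP1 was 1.24-fold higher. Interferon-stimulated genes were lower for 12 of 42 and higher for 2 (15 and 2 over the list alone; camera adjusted p = 0.000665, and adjusted p = 0.385 with an estimated correlation), with 1 higher without replicate 2 of 6A-SA5 or replicate 1 or 2 of WT-WB1. HLA-C (1.65-fold), BST2, which tethers virus particles (1.65-fold), and the ubiquitin-like modifier ISG15 (1.45-fold) were lower, and probe sets of HLA class I genes can share signal. HLA-C lay among neighbours shifted upward. Neither list was called without _x_at and _s_at probe sets (adjusted p = 0.429 and adjusted p = 0.21). The stress list then had 3 lower and 2 higher members, and the interferon list 4 and 0.

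The identity of the cells as luminal and hormone-responsive showed changes in single genes in both directions. Estrogen receptor targets were higher for 11 and lower for 9 of 33 (13 and 11 over the list alone, camera adjusted p = 0.918), and their median (−0.03) and mean (−0.08) were negative while camera's direction was up. By fry the list was lower (adjusted p = 0.01). Without replicate 3 of either clone, and with the replicate block, 7 were higher. GREB1 (1.66-fold) and TFF3 (1.79-fold, in an upward run) were higher, and the fatty acid elongase ELOVL2 (4.64-fold), RAB31 (2.54-fold) and the protease PRSS23 (1.64-fold) were lower. ELOVL2 lay among neighbours shifted upward. Luminal genes were higher for 4 and lower for 6 of 25 (4 and 10 over the list alone, camera adjusted p = 0.0935). The list was called lower without genes in shifted runs (adjusted p = 0.0252, and adjusted p = 0.3 with an estimated correlation) and by fry (adjusted p = 0.017). Without _x_at and _s_at probe sets 2 were higher and 2 lower. The receptor kinase ERBB4 was 2.41-fold lower, with a log2 difference of −0.58 as the mean of its probe sets. The epithelial transcription factor SPDEF (1.49-fold, in an upward run, or a log2 difference of 0.30 as the mean of its probe sets) and the prolactin receptor PRLR (1.46-fold) were higher, and ESR1 was 1.17-fold higher. Basal and myoepithelial genes were higher for 1 and lower for 4 of 20 (1 and 5 over the list alone, camera adjusted p = 0.345), with ACTG2 1.95-fold higher and CAV1 (1.42-fold) and OXTR (1.32-fold) lower. As the mean of its probe sets ACTG2 differed by 0.47, against 0.97, and 3 basal genes were higher in that setting.

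Insulin and growth factor genes were higher for 3 and lower for 9 of 37 (7 and 10 over the list alone, camera adjusted p = 0.731), with a median of 0.01 and a mean of −0.03, and fry called the list lower (adjusted p = 0.0428). The higher members numbered 5 without replicate 1 of 6A-SA5, after subtraction of array medians or as means of all probe sets, and 7 with trended and robust eBayes or among bright probe sets. With all arrays, the 3 higher genes were all receptors: FGFR4 (1.75-fold), MET (1.61-fold) and IGF1R (1.52-fold). The probe sets of FGFR4 averaged a log2 difference of 0.46, against 0.81 for the brightest. The binding proteins IGFBP5 (1.51-fold), IGFBP6 (1.46-fold), IGFBP4 (1.37-fold) and IGFBP2 (1.37-fold) were lower. Immediate early genes were higher for 4 and lower for 6 of 25 (5 and 10 over the list alone, camera adjusted p = 0.0931). KLF4 (1.66-fold) and IER5 (1.30-fold) were lower and SRF, in an upward run, 1.46-fold higher. Without replicate 3 of either clone this list was called lower (adjusted p = 0.0439 for 6A-SA5 and adjusted p = 0.00634 for WT-WB1), as it was without genes in shifted runs (adjusted p = 0.0124) and by fry (adjusted p = 0.0249). With an estimated correlation the camera calls were lost (adjusted p = 0.434, adjusted p = 0.229 and adjusted p = 0.278). The higher members numbered 2 without replicate 3 of 6A-SA5 or replicate 1 or 2 of WT-WB1 and 1 without _x_at and _s_at probe sets, and 10 were lower with trended and robust eBayes.

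Hypoxia and glycolysis genes were higher for 2 and lower for 7 of 29 (3 and 10 over the list alone, camera adjusted p = 0.0915), and without replicate 2 of 6A-SA5 the list was called lower (adjusted p = 0.0462). It was also called without genes in shifted runs (adjusted p = 0.0252) and by fry (adjusted p = 0.01), but an estimated correlation ended both camera calls (adjusted p = 0.389 and adjusted p = 0.301). Only 1 member was higher without replicate 3 of 6A-SA5 or replicate 1 or 2 of WT-WB1, and without _x_at and _s_at probe sets 1 was higher and 4 lower. The glycolytic regulator PFKFB3 (2.40-fold) and the oxygen sensor EGLN3 (1.68-fold) were lower, and VEGFA, in an upward run, was 1.41-fold higher, with a log2 difference of 0.31 as the mean of its probe sets. Cholesterol and fatty acid genes were higher for 5 and lower for 3 of 24, also over the list alone (camera adjusted p = 0.957), with 5 lower under trended and robust eBayes. SREBF2, a master regulator of sterol synthesis, was 1.53-fold lower in a downward run, whereas LSS (1.40-fold) and ELOVL6 (1.33-fold) were higher. NF-κB targets and cytokines were higher for 3 and lower for 4 of 28, also over the list alone (camera adjusted p = 0.918), with 1 higher without replicate 2 of 6A-SA5 or replicate 3 of WT-WB1. S100A8 was 1.64-fold higher, a call that ended without _x_at and _s_at probe sets (log2 difference 0.05, adjusted p = 0.788), and LIF (1.25-fold) and TNFAIP2 (1.24-fold) were lower. The means over all probe sets were 0.38 for S100A8 and −0.15 for TNFAIP2.

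Markers of other cell types were not called as groups by camera. Of 15 fibroblast markers 0 were higher and 2 lower, COL5A1 and the dim COL3A1, which are also in the matrix list (camera adjusted p = 0.143), but fry called the list lower (adjusted p = 0.0175). Without _x_at and _s_at probe sets, or among bright probe sets, 1 was lower. Of 16 leukocyte markers LCP1 was 1.21-fold higher and CORO1A 1.23-fold lower (camera adjusted p = 0.378), and CORO1A lost its call without replicate 3 of 6A-SA5 (log2 difference −0.27, adjusted p = 0.0532) and at an adjusted p under 0.01 (adjusted p = 0.0115). Among bright probe sets 2 leukocyte markers were lower. None of the 12 endothelial markers passed in limma's test (camera adjusted p = 0.575), but 1 was lower without replicate 1 of 6A-SA5. The counts over these lists alone were the same.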

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

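Removing genes in shifted runs was chosen after seeing the data, and the other alternatives were planned. Of 1263 values of the 92 named genes under the settings fixed beforehand that give single genes a value, 1254 stayed on their side of the threshold and 9 lost the call, and 0 called genes reversed. Of those 9, 7 were lost without _x_at and _s_at probe sets (NUP62CL, FN1, GSN, S100A8, FAS, GDF15 and COL3A1), where a dimmer probe set stood for the gene, and CORO1A was lost without replicate 3 of 6A-SA5 and at an adjusted p under 0.01. The stability of the named genes was largely built in, as most were chosen for large differences or small p-values on these same arrays. Without _x_at and _s_at probe sets 19 named genes had no value, and among probe sets above the median brightness 6 had none. As the mean of all probe sets, 28 of the 90 called named genes moved by over 1.5 times, all still called.

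Without _x_at and _s_at probe sets, 1987 probe sets were higher and 1740 lower, 122 of them at least 2-fold lower, among fewer probe sets tested, and 6 lists were called. Lost were TGF-β/SMAD targets, extracellular matrix, EMT, interferon and unfolded protein response, and Rho regulators were added; the cause was not tested. At an adjusted p under 0.01 there were 1840 higher and 1894 lower probe sets and 859 higher and 986 lower genes, by construction of the stricter threshold. Camera with an estimated correlation called 0 of the 25 lists (4 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 19. Those added by fry, all lower, were receptors and ligands, Rho, actin, estrogen receptor targets, luminal, insulin, immediate early, hypoxia and fibroblast genes. Without genes in shifted runs 989 genes were higher, since most runs were upward, 1300 were lower, and 15 lists were called, with Rho, actin, luminal, immediate early and hypoxia genes added, all lower. An estimated correlation left 0 lists called in this setting (6 at an unadjusted p under 0.05; smallest adjusted p = 0.184) and 0 in every other (0 to 7 unadjusted).

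Leaving out each array in turn gave 2134 to 3479 higher probe sets and 970 to 1418 higher genes, lowest in both cases without replicate 2 of 6A-SA5. There 2188 of the 2232 called genes were among the original 3022, and the rest of the 3022 lost their call. The number of the 3022 that stayed called ranged from 2155 (without replicate 3 of WT-WB1) to 2640 (without replicate 1 of 6A-SA5). Lower genes ranged from 1144 to 1528, probe sets at least 2-fold lower from 195 to 220, and called lists from 10 to 12. With the replicate block, 1305 genes were higher and 1360 lower and 11 lists were called. Deviations of same-numbered arrays correlated at −0.04, 0.08 and −0.12, so no shared effect of the number was visible. Whether same-numbered samples were handled together is not known here. After rescaling the median difference of all probe sets was 0.00396 (quantile) or 0.012 (array medians), against −0.00174 before, and 83.3% to 84.8% of the 2-fold differences were decreases.

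The 10 splits of the 6 arrays into 3 and 3 are too few to judge by. The clones' own split called 6355 probe sets, 243 of them at least 2-fold, and 3022 genes, against highest other values of 1, 1 and 0. It called 10 lists. The other splits, which mix the clones, each called 0 genes but 1 to 8 lists. Mixed groups keep part of the clone difference in their means and put the rest into the spread within groups. The 0 genes were therefore largely built in, and the list calls may carry the clone difference, so these splits cannot judge camera. A list call at camera's preset correlation remains limited evidence here, because an estimated correlation left 0 lists called. Dim probe sets lie near background, where RMA values differ little, so changes in weakly expressed genes can be missed.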

Other observations

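All tests below concern patterns noticed in these data. The tests with spike-in controls, with GAPDH and STAT1, and of genes outside the shifted runs were chosen only after the results were seen, as was the margin (bootstrap SD of the median) by which the second p53 list and the NRF2 list were read. The other tests were fixed before their own result.

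Neighbouring genes tended to differ in the same direction. Over 13174 expressed genes in chromosomal order, 22 runs held 1317 genes, 18 of them higher and 4 lower in 6A-SA5. The longest, from EIF4ENIF1 to SHANK3, held 198 genes, of which 90.9% were lower, 127 past the threshold against 1 higher, with a median log2 difference of −0.33. It includes TIMP3, BIK, PARVB, MYH9, SREBF2, MCM5 and ATF4, named above for their functions. Further downward runs, EYA1 to MTDH (69 genes, median −0.18) and NIPAL2 to SLC25A32 (23 genes, median −0.15), hold MMP16, TP53INP1 and RRM2B, and another ran from LY6E to RECQL4 (50 genes, 94% lower). Among the upward runs were FBXO25 to MTMR9 (23 genes, median 0.28), NCR2 to EEF1A1 (107 genes, median 0.27), HLA-DQB1 to ZFAND3 (72 genes, median 0.27) and LYSMD2 to GRAMD2A (107 genes, median 0.21). Runs of a called gene's own direction held 25.5% of the 2727 called genes that could be ordered.

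Shuffling the gene order gave no window as far from 0 (largest 0.281 against 0.604; permutation p = 0.000999, the smallest that 1000 shuffles can give), which argues against chance order. Families of related neighbours do not account for it either, since 95.5% of the runs remained with 1 gene per family. Where every second gene was used to find runs, 88.4% of the 242 left-out genes moved with them, against 49.5% on average and at most 62.8% in shuffles. A difference in DNA copy number between the clones is a candidate explanation and predicts this, but regulation of whole chromosomal domains predicts it too, and no DNA was measured here. Single arrays set against the others of their clone gave 0 to 3 runs with window medians of at most 0.144.

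Differences of at least 2-fold were mostly decreases, 207 against 36 probe sets. An error of scaling would need an offset of 0.25 log2 to balance these, with the called probe sets held fixed. The hybridisation spike-in controls (18 probe sets, reading only bioB, bioC, bioD and cre) differed by a median of 0.0238 (standard error 0.0541 over array means). This argues against an offset of that size, as far as these few transcripts can show. Shifted runs do not account for the excess of decreases. Outside runs of their own direction, 82 genes were at least 2-fold lower and 10 higher, 89.1% lower (exact 95% binomial interval 80.9% to 94.7%). The interval treats genes as independent trials, but related genes such as AKR1C1, AKR1C2 and AKR1C3 may move together, so it may be too narrow. What stays open is whether the excess of decreases belongs to the *6A receptor or to other differences between the clones, since each construct is represented by 1 clone.

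The p53 target and apoptosis list was lower as a whole at camera's preset correlation (adjusted p = 2.59e-09, and adjusted p = 0.234 with an estimated one), and 3 of its 14 called members lay in downward runs. It mixes p53 targets with apoptosis genes, so its shift does not measure p53 activity alone. Its 17 members outside the runs (adjusted p = 2.79e-07 and adjusted p = 0.184) still had a median of −0.2927, below the −0.0806 that bounds the lowest 2.5% of random lists outside the runs matched on expression, so the runs are not the whole of it. RNA integrity stays open, because the 3′ minus 5′ signal of GAPDH differed by −0.00675 log2 but lay near the top of the array range, and that of the dimmer control STAT1 by −0.0166 with a standard error of 0.143. Lower p53 activity may contribute, but a second list of 35 measured p53 targets that shares no member with the first had a median of −0.0496 (bootstrap SD 0.0512), at the lower bound of its random lists (−0.0497), with 10 members lower and 6 higher. Of the higher members POLH, PTP4A1 and FBXO22 lay in upward runs, and the 29 members outside runs had a median of −0.127 (bootstrap SD 0.046; random lists −0.0567 to 0.0433; camera p = 0.0042, and p = 0.0977 with an estimated correlation), but this was read only after the whole list, so p53 activity stays open.

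The aldo-keto reductases AKR1C1 (2.90-fold), AKR1C2 (3.21-fold) and AKR1C3 (8.52-fold) were all lower in 6A-SA5, although their probes may cross-hybridise. They are known targets of NRF2, the regulator of antioxidant genes, which led to the hypothesis of lower NRF2 output. A list of 25 other NRF2 targets had 23 measured members, of which 9 were lower and 1 higher, with a median of −0.177 (bootstrap SD 0.0581; random lists matched on expression −0.0592 to 0.0715). TXNRD1 (1.34-fold), HMOX1 (1.45-fold, in a downward run) and SLC7A11, which also belongs to the ATF4 list, were lower, whereas GCLC, in an upward run, was 1.20-fold higher; the 21 members outside runs had the same median, −0.177 (random lists −0.0627 to 0.0609). Lower NRF2 output predicts such a shift, but camera gave p = 1.15e-05 at the preset correlation and p = 0.131 with an estimated one. The NRF2 gene itself, NFE2L2, did not pass (log2 difference −0.08, limma adjusted p = 0.469). Its transcript level does not measure the activity of the protein, so this value cannot decide the hypothesis.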
